A study of Mus musculus with 4 samples.

How the data were processed

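Single-nucleus RNA sequencing was analysed from 4 liver libraries of mice, 2 from mice fasted for 16 to 24 h and 2 from fed controls. Per the labels' protocols, each library was a preparation of nuclei from pooled frozen liver (50 mg, 8 mice), loaded on a 10x Genomics controller with chemistry 3.1. Neither strain, sex, age nor time of day is given in the sources used here. The labels do not say whether the 2 preparations of a group came from the same mice. The p-values below, apart from camera's for gene lists, therefore measure the spread between preparations and not the spread between mice. Part or all of that spread may be technical. The replicate numbers carry no stated batch and were not used to pair libraries.

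Per the submitters' processing notes, reads were aligned to mm10 with Cell Ranger 6.0. The deposited matrices hold raw counts of unique molecular identifiers (UMIs, 1 count per captured transcript) for 32285 gene symbols and 11770, 7499, 9736 and 5396 barcodes in fasted 1, fasted 2, fed 1 and fed 2. The other deposited content is barcode and gene symbol lists with no measured values. Every stored value was a whole number of 0 or more. Between 13.2% and 17.0% of the stored entries per matrix were 0, which a plain count matrix does not store. Some entries may thus have been lowered before deposit, by a step that is not given in the sources used here. Counting each stored 0 as 1 was tried as an alternative.

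Total UMIs were 30955600, 24139311, 22924339 and 8078755, with medians of 1610.5, 2349, 1589.5 and 1042 per barcode, in the same order. Nuclei with at least 500 genes and at most 5% mitochondrial UMIs were used, 11266, 7059, 9585 and 4379 by genes alone. Doublets were scored per library with Scrublet in scanpy 1.11.5 (expected rate 0.06). Its automatic threshold marked 1778, 1, 1 and 0 barcodes. The highest-scoring barcodes were removed instead, at 0.8% per 1000 barcodes loaded in the matrix, which took 1108, 450, 758 and 233 barcodes. That rule was chosen after the automatic thresholds were seen, and the automatic ones were kept as an alternative. This left 10187, 6628, 8830 and 4184 nuclei.

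Counts were log-normalised, and 2000 variable genes, 30 principal components and a graph of 15 neighbours were used for Leiden clustering (leidenalg 0.10.2, resolution 1) without batch integration. A cluster took the name of the cell type whose fixed markers had the highest mean relative level in it, provided that at least 3 of them were detected in at least 10% of its nuclei. It was left unnamed where markers of another type were more frequent among its 10 leading genes, where at least 5 of these were mitochondrial, or where it was shallow without a leading marker. No cluster met the markers of fibroblasts or smooth muscle, or of neutrophils. Libraries were the unit of replication, with raw counts summed per library over the nuclei of a type. Types with at least 20 nuclei in every library were tested, which were 6.

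Genes were compared with quasi-likelihood F tests in edgeR 4.0.16 (robust fit, trimmed mean of M values (TMM) scaling, filterByExpr) in R 4.3.3. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and standard errors (SE) were taken as the log2 fold change over the root of the F statistic. DESeq2 1.42.0 (Wald test) was the other tool. Levels are given as CPM, the usual scaled share of a library's summed counts, and all log2 fold changes are fasted minus fed. Summed hepatocyte counts were 21031993, 19382335, 16851895 and 6772407. The scatter between the libraries of a group lay far beyond counting noise, with a chi-square per degree of freedom of 205 in fasted and 289 in fed. That figure is weighted toward abundant genes, and for genes with few counts depth limits the precision as well.

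Gene groups were 22 fixed lists, tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over the lists. Camera compares a list with all other genes. With the preset its p-values rest on the spread across genes and not between libraries. With an estimated correlation they rest on the few residual degrees of freedom of the libraries. That setting and fry (limma) were the alternatives. In types other than hepatocytes, a gene counted as the type's own when its CPM was at least 2 times that of hepatocytes.

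Hepatocytes were placed along the axis from portal to central vein by a score per nucleus. The score was the mean z-score of 11 pericentral landmark genes minus that of 9 periportal ones, those of 12 and 11 fixed landmarks detected in at least 2% of hepatocytes in every library. It was computed on counts thinned to 1500 UMIs. Shallower nuclei were left out, which left 4821, 4235, 4341 and 1570 scored. Scores from odd-numbered and from even-numbered landmarks correlated across nuclei at 0.548, 0.569, 0.508 and 0.523. Nuclei were split by score into 3 bins of equal size, and counts of the lowest and highest bin were summed per library and fitted in edgeR with library as a block. A gradient is the log2 ratio of the pericentral to the periportal bin, and the difference is the gradient in fasted minus that in fed. Landmarks themselves were not tested.

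Named in the text by rule were these genes. In hepatocytes they were up to 10 risen and 10 fallen genes of largest fold past the threshold, every bile acid synthesis gene, and up to 4 genes of smallest p from each other list. In other types they were up to 5 own genes each way. For gradients they were the bile acid synthesis and transport lists and up to 5 genes each way for the difference, with a mean of at least 20 CPM. Lists, markers, landmarks, tests, this rule and most alternatives were fixed before the data were examined. Other genes named were chosen after their values were seen, as stated with them.

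Shares of nuclei carry exact Clopper-Pearson 95% intervals per library and a two-sided exact permutation test, whose smallest p with 2 against 2 libraries is 0.333. Intervals cover counting error only. Gene positions are from the GENCODE annotation of GRCm38 (mm10), matched by symbol.

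The fits were tested on simulated data, negative binomial counts with the means, library sizes and dispersion trend of the real sums and with known changes added. In hepatocytes 4.69%, 48.5% and 90.8% of genes changed by log2 1, 2 and 4 were called, so simulated changes of up to 2-fold mostly went uncalled. In endothelial nuclei the shares were 7.81%, 56.5% and 95.2%, and for the gradient difference 60.0%, 81.8% and 92.4%. Each simulated gene took the dispersion trend without a scatter of its own, so the shares in the real data may be lower. In the real hepatocyte sums Cyp2c70, at log2 -4.12, had an edgeR adjusted p of 0.508.

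Alternatives changed 1 choice at a time. They covered RLE in place of TMM scaling, no low-count filter or a mean of at least 10 CPM, DESeq2, the replicate number as a block, and leaving out each library in turn. Nuclei were taken with doublets kept, from all barcodes or with at least 1000 genes, and sums were thinned to the smallest library. The position score was recomputed with 1000 UMIs, without thinning, as a log ratio, from odd or even landmarks and with the outer of 5 bins. Leiden resolution 0.5 was tried for the shares. Chosen after seeing the data were the automatic doublet threshold, stored zeros as 1, and leaving out an acute phase cluster or 4 genes that collect ribosomal RNA reads. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.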

Results

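Livers of fasted and fed mice were compared, 2 libraries of nuclei per group, to ask how feeding changed hepatocyte genes, bile acid genes among them, and their position along the lobule. After filtering, 29829 nuclei formed 23 clusters. Hepatocyte-like nuclei, marked by genes such as Alb and Apob, numbered 18843 in 12 clusters, most of which came mainly from 1 library. The remaining named clusters were endothelial-like (5411 nuclei), Kupffer cell- or macrophage-like (1963), stellate-like (1672), T or NK cell-like (548), cholangiocyte-like (510), B or plasma cell-like (423), mesothelial-like (115) and dendritic cell-like (89). These names are used without the suffix from here on. The 2 unnamed clusters held 255 nuclei. Fed 2 was the shallowest library, with a median of 1282 UMIs per hepatocyte against 2928 in fasted 1, 3240 in fasted 2 and 2553.5 in fed 1. Gm42418, a gene that collects ribosomal RNA reads, took 4.61% of UMIs in fed 2 against 0.204%, 1.01% and 0.338% in the same order.

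**Figure D1:**
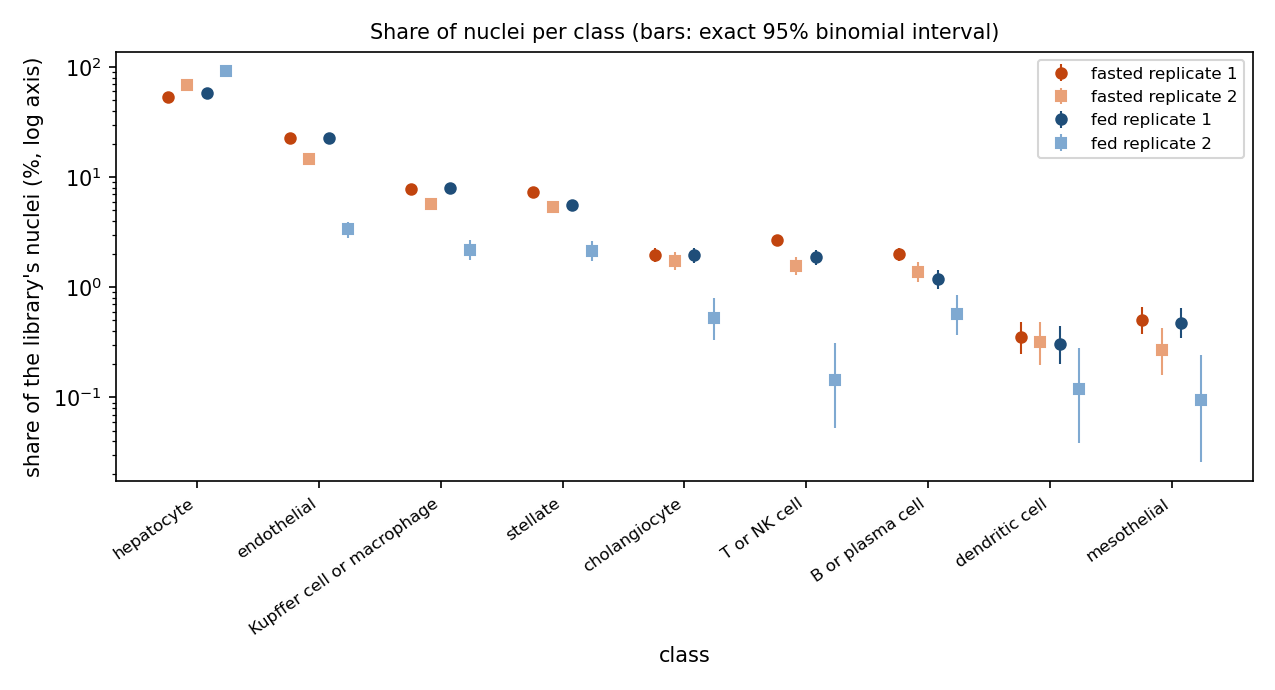
Share of nuclei (percent, log axis, vertical) in each named cell type (horizontal) for the 4 libraries (points), with exact 95% intervals (bars). Hepatocytes made 90.8% of nuclei in fed 2 and between 53.1% and 69.0% in the other libraries.

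Hepatocytes of fasted mice carried far more RNA of Cyp4a14, an enzyme that hydroxylates fatty acids and a target of the fatty acid receptor PPAR-alpha, than those of fed mice. Genes for burning fatty acids, making glucose and breaking down amino acids were higher in fasted hepatocytes as groups. Genes for making fat and cholesterol, which insulin and sterol-sensing factors drive, were lower as groups. Each of these group calls by camera was lost at adjusted p = 0.180 with an estimated correlation. Cyp4a14 (chromosome 4, 115486200 to 115496142, minus strand) was at 915 and 888 CPM in the fasted libraries and at 4.51 and 6.94 CPM in the fed ones. Its log2 fold change was 7.27 (SE 0.46, n = 2 and 2; edgeR adjusted p = 0.0400). It was the only gene of 13994 that passed over all genes. With RLE scaling the adjusted p of Cyp4a14 in hepatocytes was 0.0513 in edgeR, with stored zeros counted as 1 it was 0.0859, and over its other alternatives in edgeR it ran from 1.21e-43 to 0.0469. No gene fell in edgeR, and DESeq2 called 75 higher and 88 lower. Of the 13994 genes, 950 had an unadjusted p under 0.05 in edgeR, where chance alone gives a share of 0.05. The groups did not overlap for 36.2% of genes, against 33.3% that chance gives. Without fasted 1, fasted 2, fed 1 or fed 2 in turn, edgeR called 8, 3, 224 and 245 genes, and without the low-count filter 270.

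Of the 22 gene lists, 13 passed camera, 7 higher and 6 lower in fasted hepatocytes. None passed with an estimated correlation, where the smallest adjusted p was 0.180, or with fry, where it was 0.137. The calls thus appeared only with camera's preset setting. With an estimated correlation camera takes the few residual degrees of freedom of the libraries in place of those of the genes. That change alone raises its p-values, so the losses do not show that correlated genes undid the calls. The estimated correlation was 0.000852 for gluconeogenesis and -0.0376 for lipoprotein and phospholipid genes, below the preset 0.01. Both of these calls were lost as well, and camera's unadjusted p for gluconeogenesis went from 3.61e-05 to 0.0486.

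**Figure D2:**
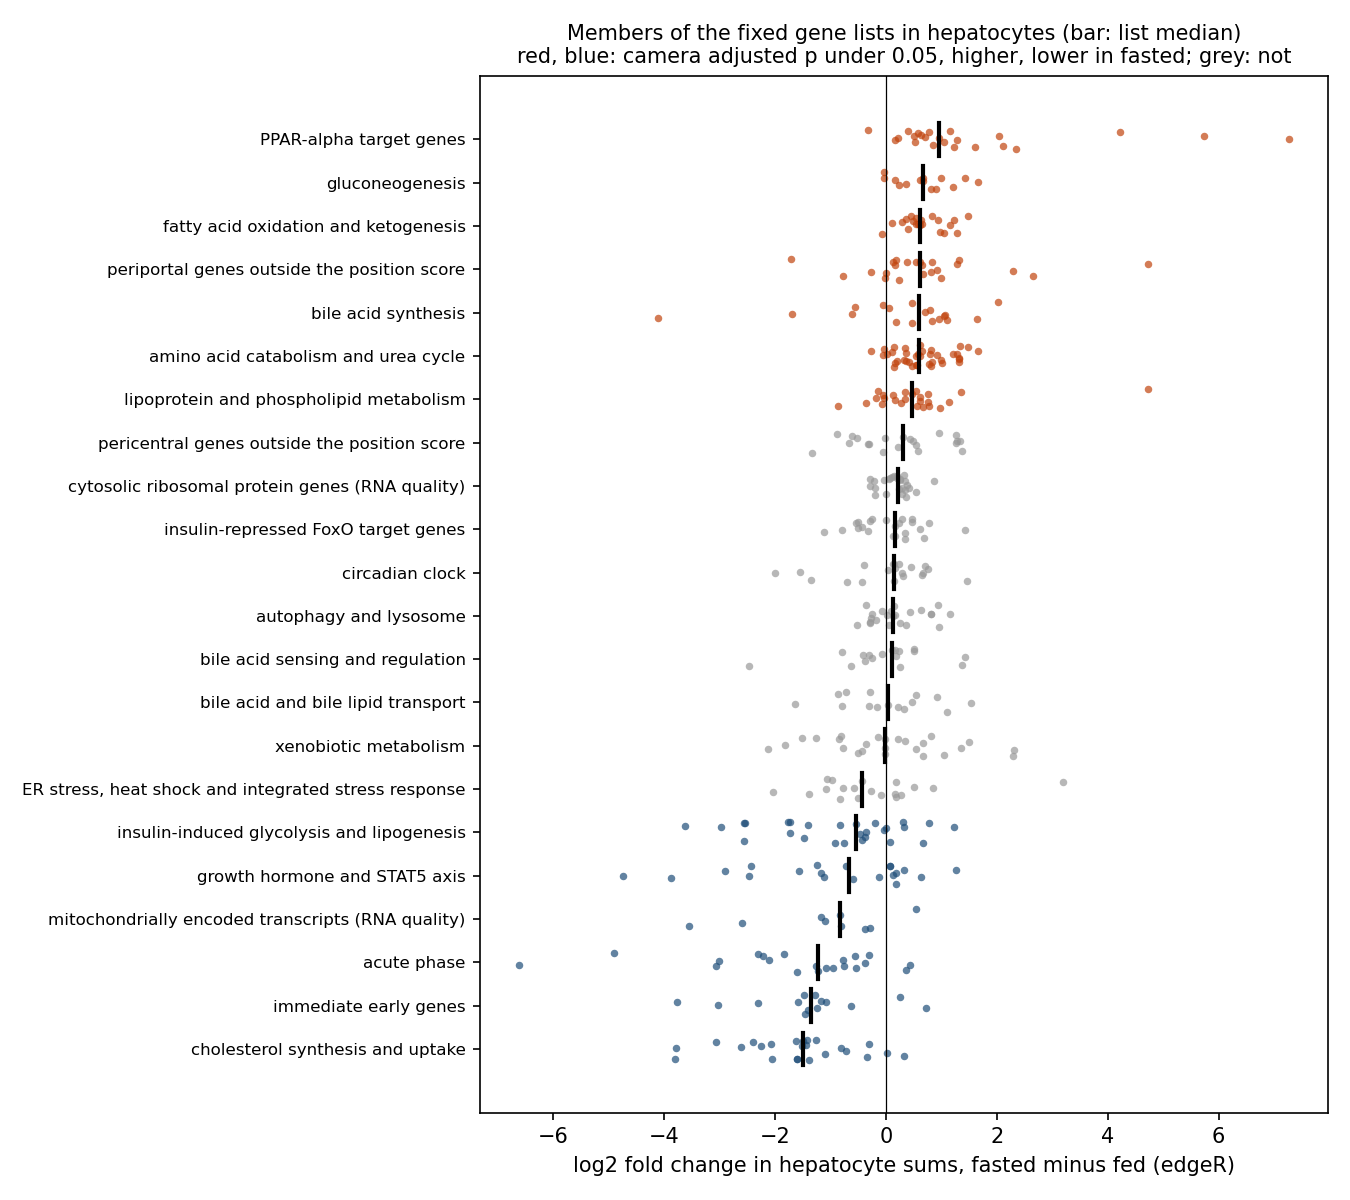
Log2 fold change in hepatocytes, fasted minus fed (horizontal axis), of the members (points) of the 22 gene lists (vertical axis) and their medians (black bars), with lists past camera's threshold in red (higher) or blue (lower). The medians run from -1.50 for cholesterol synthesis and uptake to 0.96 for PPAR-alpha targets.

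Genes of bile acid synthesis were mixed. Cyp7a1, which starts the classic route from cholesterol, Cyp8b1, which adds the hydroxyl group of cholic acid, and Cyp27a1, which starts the alternative route, had higher values in both fasted libraries than in both fed ones. Cyp7b1, which continues the alternative route, and Cyp2c70, which makes the mouse muricholic acids, had lower ones. Cyp7a1 (chromosome 4, 6265612 to 6275633, minus strand) was at 461 and 193 CPM in fasted and 120 and 85.1 CPM in fed, a log2 fold change of 1.64 (SE 0.46). Cyp8b1 was at 20.2 and 9.91 CPM against 1.48 and 5.76 CPM, or 2.02 (SE 0.77). Cyp27a1 was at 549 and 442 CPM against 312 and 232 CPM, or 0.83 (SE 0.31). Cyp7b1 (chromosome 3, 18071950 to 18243338, minus strand) was at 967 and 935 CPM against 4880 and 1305 CPM, or -1.70 (SE 0.59). Cyp2c70 (chromosome 19, 40153353 to 40187333, minus strand) was at 44.4 and 12.4 CPM against 793 and 182 CPM, or -4.12 (SE 0.89), and was the only member that DESeq2 called (adjusted p = 2.05e-06). Cyp2c70 belongs to a gene family with similar sequences, so shared reads are possible. Without fed 1, Cyp7b1 in hepatocytes had -0.56, Cyp8b1 in hepatocytes 1.26 and Cyp2c70 in hepatocytes -2.81, and without fed 2 these had -2.33, 3.36 and -4.79. Without fasted 1, Cyp7a1 in hepatocytes had 0.91, while Cyp8b1 had 1.43 and Cyp2c70 -5.27, or -3.49 without fasted 2. In edgeR none of the 18 members passed over all genes and none did adjusted over the list alone, where Cyp2c70 came nearest at 0.0595. Without fasted 1, fasted 2, fed 1 and fed 2 in turn, 1, 2, 4 and 6 members passed adjusted over the list alone.

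In all, 11 bile acid synthesis genes were higher in both fasted libraries than in both fed ones and 2 were lower, with 13 fold changes above 0 and 5 below. As a list they were higher in fasted (median log2 fold change 0.59, camera adjusted p = 0.0222), a call lost at adjusted p = 0.488 with an estimated correlation. It was also lost without fasted 1 (adjusted p = 0.514) and without fed 2 (0.803). Further members were Slc27a2 and Acot8, which activate bile acid intermediates or split their thioesters, at 0.96 and 1.10, and Acox2 and Hsd17b4, which shorten their side chain in peroxisomes, at 1.04 and 0.71. Cyp39a1 was at 1.06, Akr1d1 at 0.79, Baat, which conjugates bile acids with taurine or glycine, at 0.48, and Slc27a5 at 0.47. Amacr (0.18), Akr1c6 (0.06), Pex5 (-0.05), Hsd3b7 (-0.55) and Scp2 (-0.62) completed the list. These last 5 changed direction, Amacr and Akr1c6 without fasted 1, Akr1c6 and Pex5 without fed 2, and Hsd3b7 and Scp2 without fed 1. Without fed 1, Cyp39a1 in hepatocytes had 1.95 and Acox2 in hepatocytes 1.84. The list's summed expression was 6421 and 5320 CPM in fasted and 10577 and 4083 CPM in fed, where Cyp7b1 alone made 4880 CPM in fed 1.

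**Figure D3:**
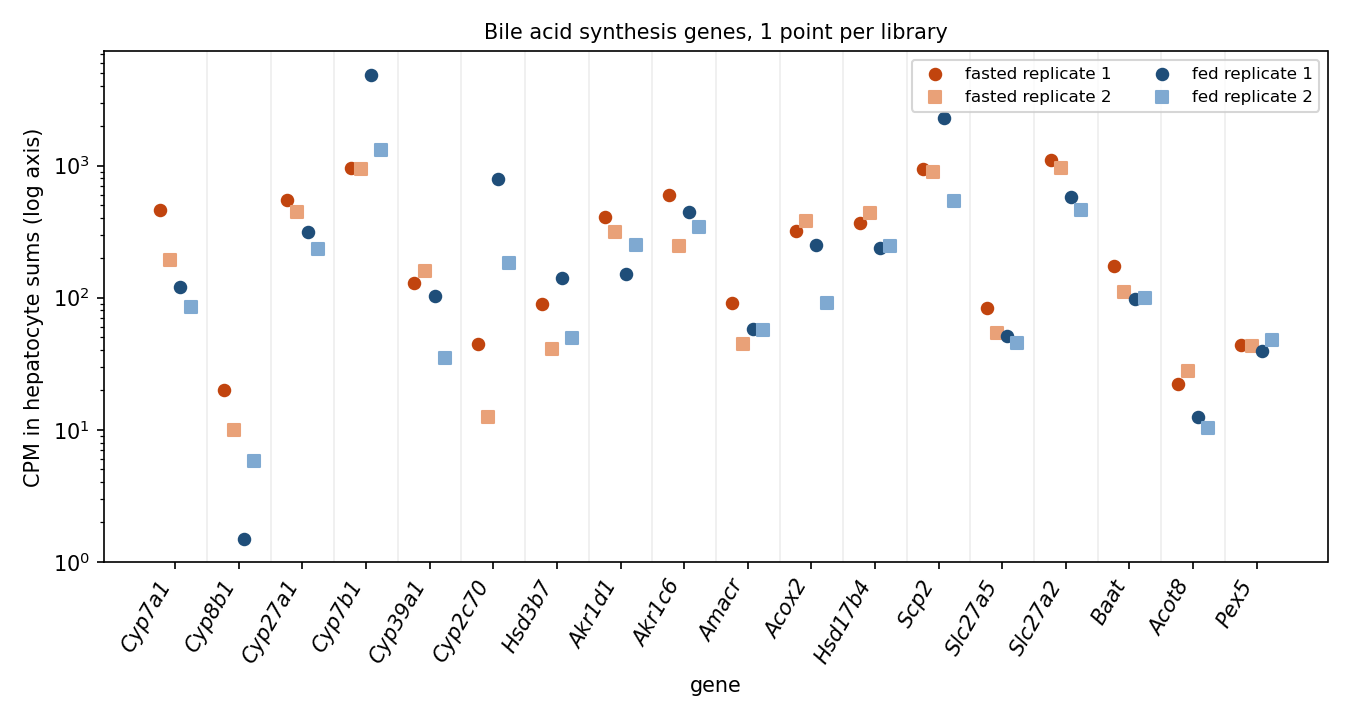
CPM on a log axis (vertical) of each bile acid synthesis gene (horizontal) in hepatocytes, with 1 point per library in 4 colours. Cyp7a1 lies between 193 and 461 CPM in fasted and between 85.1 and 120 CPM in fed, while Cyp2c70 lies between 12.4 and 44.4 CPM in fasted and between 182 and 793 CPM in fed.

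Bile acid transporters did not shift as a list (8 of 15 higher, median 0.04, camera adjusted p = 0.821), and none passed in edgeR over all genes or adjusted over the list alone. The nearest, Slco1a1, an uptake transporter, was at 265 and 160 CPM in fasted against 845 and 455 CPM in fed (-1.64, SE 0.41; DESeq2 adjusted p = 0.0348). Slco1a4, a related uptake transporter, had 1.53, Abcb4, which moves phospholipid into bile, 0.91, and Atp8b1, a lipid flippase, -0.72. Without fed 1 and without fed 2, 1 and 6 transporters passed adjusted over the list alone. Regulators of bile acids had a median of 0.11 and a mean of -0.03, camera's direction was up, and its adjusted p was 0.826. Among them Onecut1, a hepatocyte transcription factor, was at 59.4 and 65.5 CPM against 580 and 114 CPM (-2.46; DESeq2 adjusted p = 0.0104). The xenobiotic receptor Nr1i3 had 1.38 (SE 0.34), the coactivator Ppargc1a 1.42 (SE 0.45) and Nr1i2 0.50. No regulator passed in edgeR over all genes or adjusted over the list alone, but 1 did without fed 1 and 2 without fed 2. Without fed 1, Onecut1 in hepatocytes had -0.98 and Ppargc1a in hepatocytes 2.13, and without fed 2 Onecut1 had -3.18 and Slco1a4 in hepatocytes 2.40.

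Transcripts for fatty acid use were higher in fasted hepatocytes as lists, in calls that camera gave only with its preset setting. Targets of PPAR-alpha passed as a list (22 of 23 higher, median 0.96, camera adjusted p = 4.02e-20), as did fatty acid oxidation and ketogenesis (20 of 21 higher, median 0.62, camera adjusted p = 1.47e-07). Both calls were lost, each at adjusted p = 0.180 with an estimated correlation. In edgeR 6 PPAR-alpha targets rose adjusted over the list alone and 1 over all genes. Beside Cyp4a14 these included its relatives Cyp4a10 (509 and 334 CPM in fasted against 5.28 and 10.0 CPM in fed, log2 fold change 5.74) and Cyp4a31 (4.23), which may share reads with it. G0s2, an inhibitor of fat breakdown, had 71.7 and 45.8 CPM against 11.3 and 14.9 CPM (2.12; adjusted over the list alone edgeR adjusted p = 0.00922). Without fed 2, 15 PPAR-alpha targets passed adjusted over the list alone, and without fasted 1 or fasted 2, 4 did. Without fed 1 Cyp4a31 in hepatocytes had 5.09, and without fed 2 Cyp4a10 in hepatocytes had 6.34. In the oxidation list Acadm, which oxidises medium-chain fatty acids, rose adjusted over the list alone (194 and 159 CPM against 68.1 and 55.7 CPM, 1.48, SE 0.30; edgeR adjusted p = 0.0493), and no member passed over all genes. Etfdh, Ehhadh and Slc25a20, further parts of that pathway, had 1.28, 1.15 and 0.97. Without fasted 1 or fasted 2 no oxidation gene passed adjusted over the list alone, without fed 1 2 did and without fed 2 8 did.

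Glucose and amino acid genes went the same way. Gluconeogenesis was higher as a list (12 of 14, median 0.67, camera adjusted p = 8.81e-05), and so was amino acid catabolism with the urea cycle (35 of 38, median 0.59, camera adjusted p = 2.31e-09). Both calls were lost, each at adjusted p = 0.180 with an estimated correlation. In edgeR no member of either passed over all genes or adjusted over the list alone. Gpt2 and Got1, aminotransferases that feed glucose synthesis, had log2 fold changes of 1.21 (SE 0.32) and 1.65, and the mitochondrial carrier Slc25a10 had 0.91. Cth, which makes cysteine, was at 656 and 568 CPM in fasted against 188 and 235 CPM in fed (1.49), and Mat1a, which makes S-adenosylmethionine, at 2023 and 1821 CPM against 790 and 720 CPM (1.31). Gldc, which cleaves glycine, had 1.29. Without fed 1 and without fed 2, 6 and 1 gluconeogenesis genes and 16 and 4 amino acid genes passed adjusted over the list alone. Without fasted 2 Got1 in hepatocytes had 1.05. Insulin-repressed FoxO targets did not pass (13 of 23 higher, median 0.16, camera adjusted p = 0.701). In that list Pik3r1, a subunit of the insulin-signalling kinase, had -0.79, Klf15, a fasting transcription factor, 0.77 and the repressor Bcl6 -1.11. No FoxO target passed over all genes or adjusted over the list alone, though 3 did without fed 1. Bcl6 in hepatocytes had -0.41 without fed 2.

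Transcripts for making fat and cholesterol were lower in fasted hepatocytes as lists, in calls that camera gave only with its preset setting. Insulin-induced glycolysis and lipogenesis was lower as a list (20 of 27, median -0.53, camera adjusted p = 6.99e-12), and cholesterol synthesis and uptake more so (22 of 24, median -1.50, camera adjusted p = 1.06e-24). Both calls were lost, each at adjusted p = 0.180 with an estimated correlation. Adjusted over the list alone in edgeR, 9 lipogenesis and 15 cholesterol genes fell, and none passed over all genes. Thrsp, a lipogenic regulator, was at 11.1 and 14.2 CPM in fasted against 174 and 133 CPM in fed (-3.63, SE 0.36; DESeq2 adjusted p = 1.53e-14). Srebf1, the insulin-driven switch for fat synthesis, was at 15.8 and 15.7 CPM against 99.5 and 141 CPM (-2.98, SE 0.37). The fatty acid synthesis enzymes Acaca and Elovl6 had -1.76 and -1.73. Sqle, a rate-setting step of sterol synthesis, was at 3.09 and 1.81 CPM against 28.2 and 37.1 CPM (-3.78, SE 0.48). The sterol enzymes Mvd and Fdps had -3.06 and -2.62. All of these fell adjusted over the list alone. Without fasted 1 or fasted 2, 5 lipogenesis genes passed in that way, and without fasted 2, 3 cholesterol genes did.

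Lipoprotein and phospholipid genes were higher as a list (18 of 25, median 0.46, camera adjusted p = 0.00419), a call lost at adjusted p = 0.211 with an estimated correlation. Apoa4, an apolipoprotein of triglyceride-rich particles, was at 7.56 and 5.62 CPM in fasted against 0.119 and 0.443 CPM in fed (4.72, SE 0.83; DESeq2 adjusted p = 3.22e-04). It was the only member to pass in edgeR adjusted over the list alone, and none passed over all genes. Apoc2, a lipase cofactor, had 1.14, Lpin2, a step in triglyceride synthesis, 0.98 and Abca1, a cholesterol exporter, -0.86. Without fed 1 and without fed 2, 6 and 2 lipoprotein genes passed adjusted over the list alone. In the same order Apoa4 in hepatocytes had 3.76 and 5.74. Genes known as periportal were higher as a list (19 of 23, median 0.61, camera adjusted p = 7.64e-06), a call lost at adjusted p = 0.243 with an estimated correlation and without fed 2 (adjusted p = 0.143). Apoa4, which this list shares, passed adjusted over the list alone, and the lipid carrier Mfsd2a (172 and 206 CPM against 48.4 and 11.4 CPM, 2.66) and the urea cycle enzyme Asl (1.32) did not. Without fasted 1, fed 1 and fed 2, 2, 11 and 3 periportal genes passed in that way. Without fed 1 Mfsd2a in hepatocytes had 3.95 and Asl in hepatocytes 1.96, and without fed 2 Mfsd2a had 2.00. Genes known as pericentral did not pass (12 of 21 higher, median 0.32, camera adjusted p = 0.0726), but did without fasted 2 (0.0226) and without fed 2 (2.50e-04). The cation transporter Slc22a3 had 1.29, Cyp2c54 1.27 and Por, which passes electrons to cytochromes P450, 0.96. None passed over all genes or adjusted over the list alone, though 4 did without fed 1 and 4 without fed 2.

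Genes of the growth hormone and STAT5 axis were lower in fasted hepatocytes as a list (12 of 20, median -0.66, camera adjusted p = 9.37e-05). That call was lost at adjusted p = 0.428 with an estimated correlation. In edgeR 5 members fell and 1 rose adjusted over the list alone, and none passed over all genes. Hsd3b5, a male-biased steroid enzyme with close relatives, was at 9.84 and 1.65 CPM in fasted against 224 and 78.3 CPM in fed (-4.74, SE 0.94). Selenbp2, another male-biased gene, was at 70.5 and 21.0 CPM against 1111 and 227 CPM (-3.88), Cish, a feedback inhibitor of growth hormone signalling, had -2.44, and Cyp4a12b had 1.27. Without fasted 2, 3 growth hormone genes passed in that way. Without fed 1, Hsd3b5 in hepatocytes had -3.89, Selenbp2 in hepatocytes -2.44 and Cish in hepatocytes -1.66. Hsd3b5 and Selenbp2 had -6.49 and -4.96 without fasted 1 and -3.98 and -3.28 without fasted 2, and Selenbp2 -4.59 without fed 2. Clock genes had a median of 0.16 and a mean of -0.01, camera's direction was down, and its adjusted p was 0.790. The repressor Bhlhe40 fell adjusted over the list alone (33.0 and 28.0 CPM in fasted against 106 and 132 CPM in fed, -2.01, SE 0.33; edgeR adjusted p = 0.0158) and not over all genes. Its relative Bhlhe41 had -1.55, Nfil3 -1.35 and Usp2 0.70. Without fasted 1 or fasted 2 no clock gene passed adjusted over the list alone, and without fed 1 3 did.

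Immediate early genes, which respond within minutes to signals or handling, were lower in fasted hepatocytes (12 of 14, median -1.35, camera adjusted p = 2.05e-07), a call lost at adjusted p = 0.180 with an estimated correlation. Junb was at 9.94 and 6.45 CPM against 22.4 and 21.9 CPM (-1.48, SE 0.40), and Ier3, Nr4a1 and Egr1 had -3.76, -3.03 and -1.58. None passed in edgeR over all genes or adjusted over the list alone, but 7 did without fed 1. Without fed 2, Nr4a1 in hepatocytes had -1.22 and Egr1 in hepatocytes -0.71, and Nr4a1 had -3.94 without fasted 1 and -3.84 without fed 1. Acute phase genes were lower in fasted (19 of 21, median -1.22, camera adjusted p = 7.55e-05), a call lost at adjusted p = 0.644 with an estimated correlation. Without fed 1 their direction turned up (adjusted p = 0.367). Saa2, an acute phase protein with close relatives, was at 3.04 and 0.413 CPM in fasted and at 346 and 0.886 CPM in fed (-6.62, and 0.83 without fed 1). Steap4, a metalloreductase, had -3.06, Itih4 -2.21 and the heme binder Hpx -1.85. No acute phase gene passed over all genes or adjusted over the list alone, though 16 did without fed 2. Without fed 1, Steap4 in hepatocytes had -0.51, Itih4 in hepatocytes -0.66 and Hpx in hepatocytes -0.66. Without fed 2 they had -3.93, -2.94 and -2.49, and without fasted 1 Itih4 and Hpx had -3.05 and -2.63. Acute phase genes led 1 hepatocyte cluster of 1541 nuclei, of which 1532 came from fed 1, where they made 30.3% of hepatocytes.

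Genes of endoplasmic reticulum stress, heat shock and the integrated stress response did not pass as a list (12 of 19 lower, median -0.43, camera adjusted p = 0.544). They were lower without fasted 1 (adjusted p = 0.0339) and without fed 2 (2.20e-05), and higher without fed 1 (0.0246). Ddit4, a brake on mTOR, had 3.19 (DESeq2 adjusted p = 0.0224), Atf3 -2.03, Xbp1 -1.05 and the chaperone Pdia4 -0.78. None passed in edgeR over all genes or adjusted over the list alone, and without fasted 1, fed 1 and fed 2, 1, 7 and 9 did. Without fed 1, Xbp1 in hepatocytes had -0.15, Pdia4 in hepatocytes -0.17, Ddit4 in hepatocytes 4.46 and Atf3 in hepatocytes -2.85. Atf3 had -0.36 without fed 2, and without fasted 2 it had -2.66 and Ddit4 2.37. Autophagy genes did not pass (15 of 23 higher, median 0.12, camera adjusted p = 0.246), with Ctsl, a lysosomal protease, at 75.8 and 68.4 CPM against 35.8 and 27.8 CPM (1.15), Map1lc3b at 0.96, Gabarapl1 at 0.93 and Ctsd at 0.81. None of them passed over all genes or adjusted over the list alone. Xenobiotic genes had a median of -0.01 and a mean of 0.04, camera's direction was up, and its adjusted p was 0.790, or 0.0105 without fed 2. Aox3, an aldehyde oxidase, was at 633 and 489 CPM against 1239 and 1381 CPM (-1.27), Cyp2b10 had 2.32, Ugt2b1 -1.52 and Gsta2 1.36. None of these passed adjusted over the list alone or over all genes, but 8 xenobiotic genes did over the list without fed 1 and 10 without fed 2. Without fed 1, Ugt2b1 in hepatocytes had -0.56 and Cyp2b10 in hepatocytes 3.1, and Ugt2b1 had -2.11 without fasted 1.

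Of the lists that track RNA quality, mitochondrially encoded transcripts were lower in fasted (8 of 9, median -0.82, camera adjusted p = 5.29e-04), a call lost at adjusted p = 0.544 with an estimated correlation. It was also lost without fasted 2 (adjusted p = 0.924), without fed 1 (0.320) and with stored zeros counted as 1 (0.815). The list summed to only 60.5 and 9.18 CPM in fasted against 85.1 and 43.7 CPM in fed, so that the groups overlapped. Its member of smallest p, mt-Nd4, had -3.56. None passed in edgeR over all genes or adjusted over the list alone, and without fasted 1, fasted 2, fed 1 and fed 2, 5, 1, 1 and 1 did. Ribosomal protein genes did not pass (20 of 26 higher, median 0.22, camera adjusted p = 0.206), with Rps3 at 0.86 and Rpl11 at 0.54. They were higher without fasted 2 (adjusted p = 0.00119) and without fed 1 (1.28e-08) and lower without fed 2 (0.00928). None passed over all genes or adjusted over the list alone, though 11 did without fed 1. Rps3 in hepatocytes had 2.27 without fed 1 and 0.21 without fed 2, and mt-Nd4 in hepatocytes had -5.24 without fasted 1 and -2.82 without fasted 2.

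In the other cell types the genes that passed were ones that hepatocytes express strongly. In endothelial nuclei 3 of 10209 genes passed in edgeR. Cyp4a14 rose from 1.11 and 0 CPM in fed to 692 and 488 CPM in fasted, Cyp4a10 rose from 1.11 and 14.9 CPM to 376 and 161 CPM, and the steroid enzyme Hsd3b5 fell from 83.8 and 37.4 CPM to 2.25 and 2.76 CPM. In stellate nuclei 8 of 7310 genes passed. Cyp4a14 rose from 1.66 and 0 CPM to 569 and 263 CPM and Cyp4a10 from 1.66 and 0 CPM to 351 and 135 CPM, while the betaine-using methyltransferase Bhmt and Cyp2c38 rose by log2 2.68 and 3.52. Hsd3b5 fell from 105 and 72.5 CPM to 2.34 and 0 CPM, and Cyp2c70 (-3.72), Selenbp2 (-3.36) and the coenzyme A hydrolase Nudt7 (-2.22) fell as well. In cholangiocyte nuclei 3 of 4266 genes passed. Cyp4a10 rose from 0 counts in both fed libraries to 450 and 177 CPM, Cyp4a14 rose from 9.99 and 0 CPM to 749 and 341 CPM, and Cyp2c70 fell from 260 and 286 CPM to 22.6 and 0 CPM. All of these were named after their values were seen. As means of the group where the gene was higher, the calls lay at 26.6% to 74.3% of the level in hepatocytes, and fixed hepatocyte markers lay at 39.2% to 74.4% of theirs in endothelial, 30.8% to 48.9% in stellate and 35.1% to 73.8% in cholangiocyte nuclei. In the other types the markers reached up to 90.0% in Kupffer cells, 83.4% in B or plasma cells and 101.7% in dendritic cells, each in fed 2. No Kupffer cell gene of 8166 and no B or plasma cell gene of 3375 passed in edgeR, where 236 and 115 had an unadjusted p under 0.05 and DESeq2 called 8 and 5.

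Of the genes that a type expressed more than hepatocytes did, none passed in any of these types in edgeR or DESeq2. Their numbers at an unadjusted p under 0.05 in edgeR were 71 of 2338 in endothelial, 16 of 1584 in Kupffer cell and 92 of 1713 in stellate nuclei. They were 32 of 930 in cholangiocyte and 5 of 429 in B or plasma cell nuclei, where chance alone gives a share of 0.05. Fed 2 held only 140 endothelial, 91 Kupffer cell, 90 stellate, 22 cholangiocyte and 24 B or plasma cell nuclei. Changes in these types may thus have been missed. For all genes, endothelial counts were 15, 6, 142 and 118 without fasted 1, fasted 2, fed 1 and fed 2, and DESeq2 called 18. In the same order, Kupffer cell counts were 7, 2, 8 and 6, stellate counts 12, 11, 50 and 59, cholangiocyte counts 6, 12, 0 and 16, and B or plasma cell counts 1, 4, 20 and 34. DESeq2 called 8 genes in stellate and 2 in cholangiocyte nuclei. Of the types' own genes, leaving out fasted 2, fed 1 and fed 2 gave 1, 32 and 7 endothelial calls, and leaving out fed 1 and fed 2 gave 9 and 8 stellate calls. Leaving out fed 2 gave 1 cholangiocyte call, and leaving out fasted 2 or fed 1 gave 1 B or plasma cell call.

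Along the lobule, genes graded in both groups lay almost all on the same side. Slco1b2, which takes up organic anions from blood, was pericentral in both, and of the 38 genes of amino acid catabolism and the urea cycle 19 were periportal and 4 pericentral in fed, and 18 and 3 in fasted. Of 12243 genes, 641 were pericentral and 617 periportal in fed, and 768 and 758 in fasted (edgeR). For the pericentral to periportal gradient in hepatocytes within fasted, leaving out fasted 1, fasted 2, fed 1 and fed 2 gave 519, 619, 2277 and 2292 genes. For the pericentral to periportal gradient in hepatocytes within fed, it gave 874, 1141, 953 and 1547. Of the 869 genes graded in both groups, 865 had the same direction. The median ratio of their fasted to fed gradients was 0.893, and the gradients of the 1915 genes graded in either group correlated at 0.813 across genes, which are not independent replicates. Of the fixed genes outside the position score, 13 of 20 pericentral ones were pericentral in fed and 16 in fasted, and 15 and 17 of 23 periportal ones were periportal.

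Bile acid synthesis was split along the lobule, and no gene of the list passed for a difference between the groups. Cyp27a1 was pericentral in fed (log2 1.08, edgeR adjusted p = 2.31e-08) and in fasted (1.01, 5.81e-09), as was Hsd3b7, which sets the steroid ring (1.22 and 1.23). Cyp39a1, which hydroxylates an oxysterol, was periportal (-1.46 in fed and -1.11 in fasted). Cyp2c70 (0.52) and Hsd17b4 (0.35) passed in fed and not in fasted (0.07 and 0.14), but the differences did not pass (adjusted p = 0.475 and 0.785). Cyp7a1 had large pericentral values that did not pass, 2.04 (SE 0.58) in fed and 2.60 (SE 0.43) in fasted. Its libraries had 2.06 and 3.38 in fasted and 2.02 and 1.94 in fed. The Cyp7a1 gradient difference did not pass either (0.56, SE 0.74, adjusted p = 0.963), yet did without fasted 1 (1.36, adjusted p = 0.0421) and without fed 2 (0.49, 0.0298). Akr1c6 had 1.80 in fed and 2.69 in fasted, without passing. Cyp8b1 (-0.26 and 0.06) and Cyp7b1 (-0.02 and 0.09) were flat within their errors, though the Cyp7b1 gradient difference (0.11) passed without fed 1 (0.44, adjusted p = 3.17e-04) and both differences changed direction without fed 2. The other 9 members did not pass in either group.

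Transporters of bile acids and bile lipids lay to the pericentral side where they were graded, 10 of 15 in fed and 8 in fasted (edgeR). Slco1b2, the main organic anion uptake protein, had 1.61 in fed and 1.34 in fasted, the exporter Abcc4 3.65 and 3.16, and Slco1a1 0.58 and 0.79. Abcc4 had only 40 and 27 UMIs in the scored ends of the fed libraries, and the Abcc4 gradient within fed was 9.45 without fed 1. The Slco1a1 gradient within fed did not pass without fed 1 (0.19, adjusted p = 0.307), and the Slco1a1 gradient difference then did (0.60, 6.50e-05). The sterol exporter Abcg8 had 0.93 and 0.47. The Abcg8 gradient within fasted did not pass without fasted 1 (adjusted p = 0.162) or fasted 2 (0.143), the Abcg8 gradient within fed did not without fed 1 (0.0504), and the Abcg8 gradient difference passed without fed 2 (-0.66, 0.00119). Abcb4 (chromosome 5, 8893717 to 8959231, plus strand) had 0.99 in fed and 0.53 in fasted, a difference of -0.46 (SE 0.11) that passed adjusted over the list alone and not over all genes (adjusted p = 0.125). Over all genes the Abcb4 gradient difference passed without fed 1 (adjusted p = 8.71e-04) and without fed 2 (6.37e-05).

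**Figure D4:**
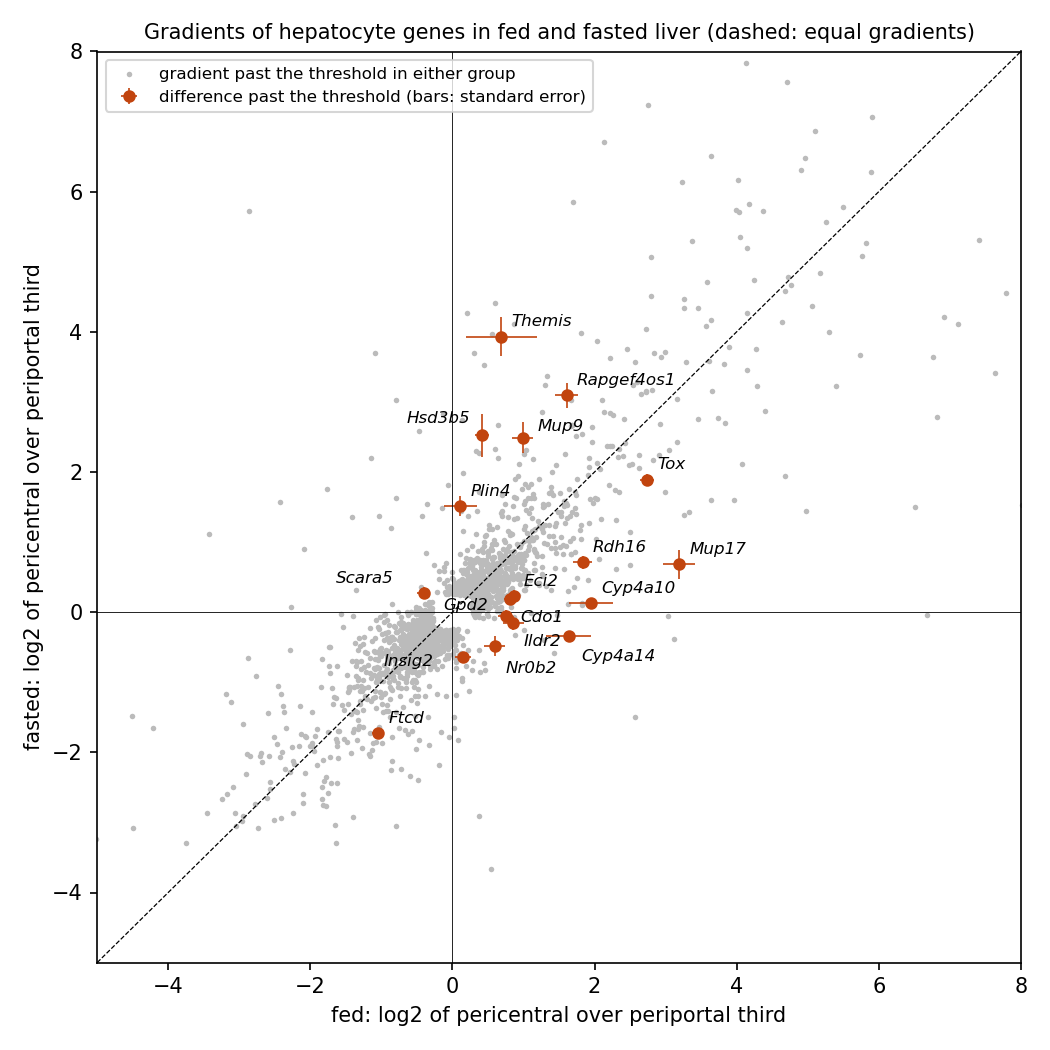
Gradient (log2 ratio of the pericentral to the periportal end) in fed (horizontal axis) and in fasted hepatocytes (vertical axis) of the 1915 genes graded in either group (grey, 8 outside the axes), with the 18 genes that differed in red with SE bars. Genes with equal gradients would lie on the dashed line, and Cyp4a14 moves from 1.64 in fed to -0.34 in fasted.

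Few genes were called as changing their position with feeding state. The fatty acid hydroxylases Cyp4a14 and Cyp4a10 were pericentral in fed hepatocytes and not in fasted ones. The steroid enzyme gene Hsd3b5 was more pericentral in fasted, and the urinary protein gene Mup17 less so. In edgeR 18 genes differed, 6 toward the pericentral side in fasted and 12 toward the periportal side. Of the 12243 genes tested, 842 had an unadjusted p under 0.05, where chance alone gives a share of 0.05. Cyp4a14 went from 1.64 to -0.34, a difference of -1.98 (SE 0.32, adjusted p = 0.00791). Its library values were -0.37 and -0.32 in fasted and 1.57 and 0.86 in fed, where only 62 and 22 UMIs lay in the scored ends. Mup17 went from 3.18 to 0.68 (adjusted p = 0.00182), the transcription factor gene Tox from 2.73 to 1.89 (0.00705) and the retinol dehydrogenase Rdh16 from 1.83 to 0.71 (0.00785). Gpd2, a mitochondrial glycerol phosphate enzyme, went from 0.75 to -0.05 (0.00791). Toward the pericentral side, Hsd3b5 went from 0.41 to 2.52 (0.00785), the antisense RNA Rapgef4os1 from 1.61 to 3.09 (0.0151) and Mup9 from 0.99 to 2.49 (0.0279). The lipid droplet gene Plin4 went from 0.11 to 1.51 (0.0342), and Scara5, a ferritin receptor, from -0.41 to 0.27 (0.0240). Hsd3b5 was at only 9.84 and 1.65 CPM in fasted hepatocytes, so its fasted gradient rests on few UMIs. Without fasted 1, fasted 2, fed 1 and fed 2 in turn, 2, 9, 217 and 259 genes differed, of which 0, 7, 12 and 18 were among these 18. All 18 kept their direction in each case.

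The bile acid regulator Nr0b2, a repressor of Cyp7a1 named here after its values were seen, went from 0.60 in fed to -0.49 in fasted (difference -1.08, edgeR adjusted p = 0.0342). Its libraries had -0.47 and -0.51 in fasted and 0.80 and -0.01 in fed, so that its fed gradient rested on fed 1. It was 1 of 4 genes with opposite gradients in the groups, with Cyp4a14, Scara5 and the Notch coactivator Maml2, whose difference did not pass (adjusted p = 0.0546).

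With at least 500 genes per nucleus, fed 2 was richer in hepatocytes, and poorer in every other named cell type, than the remaining libraries. Of its 3800 hepatocytes, 3267 lay in 1 cluster of 3368 nuclei, with a median of 1247 UMIs, the highest median doublet score of the hepatocyte clusters (0.111), and Gm42418, Lars2 and Gm26917 among its leading genes. No difference between the groups was called, since the exact permutation test used gives no p below 0.333 with 2 against 2 libraries. In the share of nuclei, hepatocytes were 53.1% and 69.0% in fasted and 57.4% and 90.8% (95% interval 89.9% to 91.7%) in fed, with a difference of -13.1 percentage points (two-sided exact permutation p = 0.667) that turned to 3.68 without fed 2. For the share of nuclei, endothelial values were 22.7% and 14.7% against 22.5% and 3.35%, and the difference of 5.79 turned to -3.77 without fed 2. In the share of nuclei, Kupffer cell or macrophage values were 7.75% and 5.69% against 7.98% and 2.17%, with a difference of 1.64 that turned to -1.26 without fed 2. Stellate cells were 7.26% and 5.33% against 5.54% and 2.15%, cholangiocytes 1.97% and 1.74% against 1.95% and 0.526%, and T or NK cells 2.68% and 1.57% against 1.87% and 0.143% (interval 0.0526% to 0.312%). B or plasma cells were 1.99% and 1.37% against 1.19% and 0.574%, dendritic cells 0.353% and 0.317% against 0.306% and 0.120%, and mesothelial cells 0.501% and 0.272% against 0.476% and 0.0956%. Without fed 2 the difference in the share of nuclei, cholangiocyte, turned from 0.617 to -0.0938, that in the share of nuclei, mesothelial, from 0.100 to -0.0895, that in the share of nuclei, stellate, shrank from 2.45 to 0.757 and that in the share of nuclei, T or NK cell, from 1.12 to 0.256. The mesothelial difference also turned without fasted 1 (-0.0141), and the share of nuclei, dendritic cell, differed by 0.122 in all and by 0.0293 without fed 2. Leaving out fasted 1, fasted 2 and fed 1 moved the hepatocyte difference to -5.11, -21.0 and -29.8, the endothelial one to 1.76, 9.82 and 15.3, and the Kupffer cell one to 0.608, 2.68 and 4.55. The permutation p of the types were 0.333 for B or plasma and dendritic cells, 1 for Kupffer cells and 0.667 for each of the rest. The shares depended on the minimum of genes and on doublet removal. With doublets kept, endothelial nuclei in fed 2 were 2.15% and dendritic cells in fasted 1 and fed 1 0.560% and 0.480%, and unnamed nuclei were 4.17% and 2.37% in fasted and 2.04% and 1.92% in fed, against 1.68%, 0.0754%, 0.872% and 0.0478% with doublets removed. With at least 1000 genes per nucleus hepatocytes were 78.5% and 91.4% in fasted against 92.9% and 98.0% in fed, endothelial nuclei 2.60% and 2.40% against 1.60% and 0.656%, and Kupffer cells 2.08% and 2.57% against 0.727% and 0.853%, so that fed 1 and not fed 2 was lowest in Kupffer cells. At that minimum 11.1% of nuclei in fasted 1 were unnamed, against 0.0428%, 0.540% and 0% in fasted 2, fed 1 and fed 2.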

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

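The test of where along the lobule the acute phase nuclei lay was set beforehand, and the other tests of explanations in this part were chosen after the results they measure were seen. The gradients of 18 hepatocyte genes differed between fasted and fed by edgeR's test of the difference itself. The differences (log2, fasted minus fed) toward the periportal side were -2.50 for Mup17, -1.98 for Cyp4a14 and -1.82 for its relative Cyp4a10. The retinol dehydrogenase Rdh16 had -1.12, the repressor Nr0b2 -1.08, the immunoglobulin-like receptor Ildr2 -1.01 and the transcription factor Tox -0.85. Gpd2, of glycerol phosphate oxidation, had -0.80, the sterol sensor Insig2 -0.79, the histidine enzyme Ftcd -0.68, and Cdo1, of cysteine oxidation, and Eci2, of fatty acid oxidation, had -0.63 each. Toward the pericentral side, the T cell gene Themis had 3.24, the steroid enzyme Hsd3b5 2.11, the urinary protein gene Mup9 1.5 and the antisense RNA Rapgef4os1 1.48. The lipid droplet gene Plin4 had 1.40 and the ferritin receptor Scara5 0.68. Themis is a fixed marker of T cells with 37 and 11 UMIs in the fed libraries, so other nuclei among the hepatocytes are a possible source, which was not tested. Nr0b2 had 0.80 in fed 1 and -0.01 in fed 2. Insig2, Ftcd, Ildr2, Cyp4a10, Cdo1, Eci2, Nr0b2 and Themis were named after their values were seen.

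A blunter position score in one group would shrink all of its gradients by 1 factor. The factor common to 859 genes graded in both groups was 0.881. After scaling the fed gradients by it, all 18 still differed by more than 3 SE. These 18 had been selected for a difference and the factor was taken from genes not called, so that count was largely set in advance. The factor itself shows little common shrinkage among those 859 genes. With odd landmarks 31 genes passed, 15 of them among these 18, and with even landmarks 22 passed, 11 of them among these, while 18 of 18 kept their direction at an unadjusted p under 0.05 with each set. Landmarks that themselves respond to feeding stay open as a source. Detection did not overlap between the groups for 8 of 20 landmarks, 4 in each set. That is near the 36.2% of all hepatocyte genes and the 33.3% that chance gives. Yet the periportal ones among them, Hsd17b13, Hal, Gls2, Ass1 and Etnppl, were all detected more often in fasted. The list of periportal genes was higher there too (19 of 23), in a camera call lost at adjusted p = 0.243 with an estimated correlation. Without the acute phase cluster of fed 1, 18 genes passed, of which 8 were among these 18, but all 18 kept their direction at an unadjusted p under 0.05, and leaving the cluster out also lowers the depth of fed 1. Feeding state may be the source, as may reads shared within the Mup, Cyp4a and Hsd3b families, which were not tested.

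Nuclei led by acute phase genes made 30.3% of the hepatocytes of fed 1 and nearly none of those elsewhere (1532 of 1541 nuclei). Free RNA of that library would reach all its nuclei alike. The 15 acute phase genes outside the leading ones were all higher in the cluster than in the other hepatocytes of fed 1. The cluster was formed on these nuclei's own expression and picked by its acute phase genes. The direction of the 15 genes was thus largely set in advance, and only the size of the gap informs. Their median log2 ratio was 1.55 (quartiles 0.90 and 2.33). Saa1, a leading gene, was at 1126 CPM in the cluster, 56.3 CPM in the other hepatocytes and 56.6 CPM in endothelial nuclei of fed 1. A position along the lobule would place most of the nuclei at 1 end, but the fullest of 3 bins of the score, the middle one, held 42.9% of the 1297 scored, with 35.2% on the periportal and 21.9% on the pericentral side. An inflammatory response in some of the mice pooled for fed 1 remains a candidate explanation, as does an effect of handling that preparation, and feeding state alone would not explain its near absence from fed 2.

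The genes that passed in endothelial, stellate and cholangiocyte nuclei were hepatocyte genes, 14 calls of 8 genes. If free hepatocyte RNA in every droplet were the source, the genes would reach these types at about the share of their hepatocyte level that hepatocyte markers reach. The median log2 ratio of these shares over the calls was 0.29, and no call reached 2 times its hepatocyte level as the mean of the group where it was higher, so free RNA would account for the calls at that level. Single libraries went above the hepatocyte level, with 9.99 against 4.51 CPM for Cyp4a14 in cholangiocytes of fed 1, 286 against 182 CPM for Cyp2c70 in cholangiocytes of fed 2 and 176 against 126 CPM for Bhmt in stellate nuclei of fed 1. In endothelial nuclei these were 14.9 against 10.0 CPM for Cyp4a10 in fed 2 and 2.76 against 1.65 CPM for Hsd3b5 in fasted 2. Summed counts were only 200203 and 17464 UMIs in cholangiocytes of fed 1 and fed 2. In endothelial nuclei they were 133851 in fed 2 and 1085099 in fasted 2. All of these values but that of Bhmt thus rest on very few UMIs, too few to tell them from counting error. A change in these types themselves stays open and was not tested separately.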

How the results depend on the processing

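The automatic doublet threshold, stored zeros counted as 1, and leaving out the acute phase cluster or the ribosomal RNA genes were alternatives chosen after the data were seen, and the others were set beforehand. With 2 libraries per group, leaving out 1 leaves a lone library that is assumed to vary like the other group. Depth limits fed 2 most, and stored zeros leave open whether entries were lowered before deposit. Clusters with at least 5% of every library's hepatocytes did not exist, so that alternative gave no value.

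Of 1562 values for 93 named hepatocyte genes, 1421 kept direction and side of the threshold, 128 newly passed, 2 no longer passed and 11 reversed. Of these genes only Cyp4a14 passed over all genes in the main fit, so no other could be lost, and the 2 losses were its own. For the rest, a kept value passed neither in the main fit nor in the alternative. The 1421 kept values thus do not show that called changes were stable. For 22 lists direction and side of the threshold were kept in 162 of 220 values, with 33 lost, 9 newly passing and 16 reversed. For 36 gradient differences they were kept in 434 of 540 (72 lost, 14 newly passing, 20 reversed), and for 54 gradients within a group in 745 of 810 (63 lost, 2 reversed). Where no reason is given for a value below, the cause was not tested.

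With RLE scaling and with stored zeros counted as 1, 0 hepatocyte genes passed. DESeq2 called 163 hepatocyte, 18 endothelial, 8 Kupffer cell and 5 B or plasma cell genes. With no low-count filter 270 hepatocyte, 45 endothelial, 24 Kupffer cell, 25 stellate and 11 B or plasma cell genes passed, and among own genes 2 endothelial, 1 stellate and 1 B or plasma cell gene did. With the replicate number as a block 18 hepatocyte, 184 endothelial, 50 Kupffer cell, 59 stellate, 30 cholangiocyte and 66 B or plasma cell genes passed, and among own genes 19 endothelial, 7 stellate and 10 cholangiocyte genes. The difference between replicates 1 and 2 correlated at 0.669 between fasted and fed across 6082 genes. That between fasted and fed correlated at 0.528 between the replicate numbers. The replicate numbers thus track a difference shared by both groups that the main tests do not take out. They mark no stated batch, so no result rests on the block. With the block the call of the bile acid synthesis list was lost (adjusted p = 0.194), and the pericentral (0.0498) and ribosomal lists (0.0453) passed.

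Leaving out 1 library gave 3 to 245 hepatocyte genes and moved Saa2 in hepatocytes from -8.62 to 0.83, the latter without fed 1. It gave 6 to 142 endothelial, 2 to 8 Kupffer cell, 11 to 59 stellate, 0 to 16 cholangiocyte and 1 to 34 B or plasma cell genes. Among own genes it gave 0 to 32 endothelial, 0 to 9 stellate, 0 to 1 cholangiocyte and 0 to 1 B or plasma cell genes. Small values changed sign. It moved Hsd3b7 in hepatocytes between -1.19 and 0.29, Akr1c6 in hepatocytes between -0.68 and 0.54, Amacr in hepatocytes between -0.39 and 0.58, Scp2 in hepatocytes between -1.29 and 0.67 and Pex5 in hepatocytes between -0.25 and 0.17. Akr1c6 in hepatocytes was also -0.149 with at least 1000 genes per nucleus, -0.0572 with the block and -0.0919 without the acute phase cluster, and Pex5 in hepatocytes was 0.00680 with no low-count filter.

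Of the lists, 0 passed with an estimated correlation and 0 with fry, 13 fewer than in camera. Without the acute phase cluster the transport and clock lists changed direction, each at adjusted p = 0.998. Leaving out 1 library changed the direction of lists, whose adjusted p then ran from 0.143 to 0.892 for bile acid transport, 0.712 to 0.815 for bile acid regulation, 0.143 to 0.738 for FoxO targets and 0.457 to 0.703 for the clock. It ran from 4.39e-43 to 0.367 for acute phase, 2.20e-05 to 0.712 for endoplasmic reticulum, heat shock and integrated stress genes, 0.0105 to 0.892 for xenobiotic and 1.28e-08 to 0.703 for ribosomal genes.

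The number of genes whose gradient differed was 99 with no low-count filter, 67 without thinning, which adds nuclei, 33 with the log ratio score, 31 with odd landmarks, 56 with outer bins of 5 and 56 with stored zeros counted as 1. Leaving out 1 library gave 2 to 259, and 519 to 2292 genes for the pericentral to periportal gradient in hepatocytes within fasted. Small differences changed sign. The Cyp27a1 gradient difference was 0.105 with the log ratio score, 0.0536 with stored zeros counted as 1 and -0.25 to 0.10 without 1 library. The Hsd3b7 gradient difference was -0.0178 with no low-count filter, -0.0483 with outer bins of 5, -0.0409 with stored zeros counted as 1 and -0.0739 to 0.41 without 1 library. Without 1 library the Cyp2c70 gradient difference was -0.65 to 0.0148, the Slco1b2 gradient difference -0.57 to 0.0667, the Abcc2 gradient difference -0.23 to 0.15, the Slco1a1 gradient difference -0.0703 to 0.60, the Cyp8b1 gradient difference -0.11 to 0.75 and the Cyp7b1 gradient difference -0.18 to 0.44. The last was -0.0237 with even landmarks. The Abcc4 gradient difference was -6.31 to 2.12 without 1 library, 0.119 without thinning, 0.694 with even landmarks and 0.586 with stored zeros counted as 1. The Mup17 gradient within fasted was -0.15 to 0.78 and the Nr0b2 gradient within fed -0.00986 to 0.82.

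With at least 1000 genes per nucleus no nuclei were named B or plasma cells or dendritic cells, so their difference in share was 0. Endothelial nuclei were then between 0.656% and 2.60% of each library.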

Other observations

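The tests of lists along the lobule in this part were chosen after the data were seen. As a list, PPAR-alpha targets lay less to the pericentral side in fasted than in fed hepatocytes (17 of 23 toward the periportal side, median difference -0.24, camera adjusted p = 1.24e-05, or 0.635 with an estimated correlation). So did fatty acid oxidation (18 of 21, -0.24, 1.24e-05, or 0.635), which shares 4 genes with that list. A shift of the whole PPAR-alpha list toward the portal vein in fasting, beyond Cyp4a10 and Cyp4a14, may lie behind this. Without both genes 15 of 21 targets still lay toward the periportal side (camera p = 2.15e-04), but with an estimated correlation p was 0.0558, so the test left the hypothesis open. The libraries' median gradients of the 23 targets were -0.13 and -0.13 in fasted and 0.17 and 0.19 in fed. Adjusted over the list alone in edgeR, 7 targets differed, 5 of them toward the periportal side, among them the fatty acid transporter Cd36 and the lipid droplet gene Plin5.

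Toward the pericentral side in fasted went gluconeogenesis (10 of 14, camera adjusted p = 0.0130, led by Pck1, Ppargc1a, Sds and Got1) and the list of endoplasmic reticulum stress, heat shock and integrated stress genes (14 of 19, camera adjusted p = 0.00787, led by the chaperones Hspa5, Pdia4 and Hsp90b1). Mitochondrially encoded transcripts, which were scarce in these nuclei, went toward the periportal side (6 of 8, camera adjusted p = 0.0130). With an estimated correlation each had an adjusted p of 0.635. The median difference of the gluconeogenesis genes was 0.06, and by median the list lay to the periportal side in both groups. Its libraries had medians of -0.33 and -0.20 in fasted and -0.35 and -0.64 in fed. Fed 1 thus lay close to fasted 1, and the shift rested on fed 2. The remaining 17 lists did not pass in this test.

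Outside the lists, Bhmt, which remakes methionine from homocysteine, was at 2342 and 1983 CPM in fasted hepatocytes against 126 and 197 CPM in fed ones (log2 fold change 3.69, edgeR adjusted p = 0.171, DESeq2 adjusted p = 4.18e-13). Nudt7, which splits coenzyme A in peroxisomes, was at 240 and 160 CPM against 1681 and 822 CPM (-2.67, edgeR adjusted p = 0.409, DESeq2 adjusted p = 5.31e-06). Cyp2c38 was at 614 and 424 CPM against 83.0 and 107 CPM (2.39, edgeR adjusted p = 0.319, DESeq2 adjusted p = 2.06e-05). These genes were chosen after their values were seen. A hepatocyte cluster of 60 nuclei was led by interferon-induced genes such as Rsad2, Ifit1 and Usp18, with 28 and 16 nuclei in fasted and 10 and 6 in fed.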
